A study of Mus musculus with 6 samples.

How the data were processed

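Mouse colon epithelial cells were profiled by bisulfite sequencing, which turns unmethylated cytosines into thymines in the reads, after capture of selected parts of the genome with the Agilent SureSelectXT Mouse Methyl-Seq system, per the labels. Per the submitters' processing notes, Bismark 0.15.0, ChIPseeker 1.10.3 and R 3.4.0 were used with build mm9; which step each served, and the settings used, are not given in the sources used here. The deposited files hold, for each sample, counts: per region the number of CpGs, the number of methylation calls over those CpGs and the number of methylated calls. That these are calls summed over CpGs, not reads, is read from the values, which grow with the number of CpGs. The same 209687 regions stand in all 6 files, with 3 to 77 CpGs and at most 500 bases between start and end. In the deposited files no value rests on fewer than 20 calls, and regions below that are blank. How the authors drew the regions, and whether duplicate reads were removed, is not given in the sources used here.

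Coordinates are those of the files. The largest end on chromosome 1 is 197093729 and on chromosome 7 it is 152509681; whether starts count from 0 or 1 is not given in the sources used here, so positions may be off by 1 base. No annotation of build mm9 was used here, and the available gene table belongs to another build, so regions were not tied to genes, promoters or exons. The gene lists fixed before the data were examined (inflammation, antioxidant response, Wnt pathway, genes methylated in colorectal cancer, epithelial identity, leukocytes, stroma, developmental factors, methylation enzymes and imprinted genes) were therefore not tested, and neither was the rule's request for 1 region per gene, for list members or for a named gene.

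The methylation level of a region is the share of methylated calls in percent. Regions needed at least 10 calls in each of the 6 samples, which the authors' own limit already met, and 179922 did. Total calls per sample ran from 24682973 to 30727568, and the median calls per region from 89 to 106. Calls from one read are not independent, and reads carry no molecular identifiers here, so no interval was drawn from calls alone. Group values are means ± SD of the 2 samples.

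The 3 comparisons used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test on methylated and unmethylated counts, a coefficient per sample for coverage and a coefficient per group for methylation, and all 6 samples sharing 1 estimate of the spread. P-values were adjusted over all regions by Benjamini-Hochberg. A call needed an adjusted p under 0.05 and group means at least 10 percentage points apart. The main test, the naming rule and most alternatives were fixed before the data were examined, and alternatives and tests chosen later are named as such where they appear. The rule names per direction the 10 regions with the largest difference among those that pass with groups that do not overlap. Where fewer pass, it names all of them and then the regions with the smallest unadjusted p up to 5 per direction, stated as not passing. Levels per sample were also averaged over all regions, per chromosome, per class of CpG density (4 classes split at the quartiles) and, as a choice made after the data were seen, per class of methylation level. Averages were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With 2 samples against 2, the exact permutation test has a smallest two-sided p of 0.333.

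Groups without a change were simulated 5 times, with each region's calls as measured and a spread estimated over all regions (intraclass correlation 0.00779), which cannot separate the spread between samples from the dependence of calls within a read. They keep the AOM/DSS samples shared between comparisons. The covariance that shared samples add was also computed from the spread between their replicates.

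The fits were tested on simulated data with 179922 regions. For AOM/DSS against control, edgeR called 38 of 100 regions changed by 40 points and 0 of 100 changed by 20 points, of which 65 had an unadjusted p under 0.05, with 0 false calls. For curcumin against AOM/DSS it called 36 and 0 of 100, and for curcumin against control 26 and 0 of 100. The changes were put only into regions of intermediate level. At such regions the test called changes of 40 points in part and missed those of 20 points. In the measured data it called a region of low level, on chromosome 10 from 77555505, at a difference of -12.0 points. In the first simulation limma 3.58.1 and the quasi-binomial model called none of the changed regions, and Fisher's exact test on summed calls called 61 of 100 regions changed by 20 points together with 1458 unchanged regions.

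The alternatives were other minimum numbers of calls, no minimum difference or 20 points, a quasi-binomial model with moderated spread, Fisher's exact test on summed calls, limma on log2 ratios, a fit with only the 4 samples compared, autosomes only, the replicate number as a block, pooled reads for mean levels, and leaving out each sample in turn. Leaving out a sample leaves its group with 1 sample, which is then assumed to vary like the other groups.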

Results

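DNA methylation was measured in colon epithelial cells of C57BL/6 mice, a common inbred laboratory strain, at 18 weeks of age. There were 3 groups with 2 samples each, 6 samples in all. Control mice were compared with mice given azoxymethane, a colon carcinogen, and dextran sulfate sodium, an agent that inflames the colon (AOM/DSS), and with AOM/DSS mice that also received curcumin, a polyphenol of turmeric. Per the labels' protocol, tumors were cut away before the epithelium was scraped off, so the values describe the epithelium that was left. Bisulfite sequencing of captured DNA gave, for each of 209687 regions, the number of methylation calls and how many of them were methylated. Regions held 3 to 77 CpGs with a median of 6.

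The control samples held 30168228 calls in replicate 0 and 24682973 in replicate 1. The AOM/DSS samples held 30727568 and 28766117 calls, and the AOM/DSS plus curcumin samples 26924351 and 26069698. The median number of calls per region ran from 89 in control replicate 1 to 106 in AOM/DSS replicate 0. All 6 samples had a value in 179922 regions (85.8%), and these were compared. Over these regions, replicates of a group differed by a mean of 4.92 percentage points in the control group, 4.77 in the AOM/DSS group and 4.58 in the curcumin group. The mean chi-square between replicates, over the 90555, 96340 and 91247 regions at 10 to 90% in each group, was 2.22, 1.94 and 1.68. It would be 1 if replicates differed only by the draw of independent calls, but calls from one read are not independent, so it does not by itself show a spread between samples. Nothing in the labels says that the replicates came from separate mice, so p-values measure only the spread between these samples.

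The first comparison, AOM/DSS against control, asks what the carcinogen and the colitis did to the methylome. Methylated regions were less methylated in both AOM/DSS samples than in both controls, by a small amount, and 7 regions passed the test for a larger change. The mean level over all regions was 41.2% ± 0.2002 (SD, n = 2) in control and 40.3% ± 0.192 (SD, n = 2) in AOM/DSS, a difference of -0.899 points. Both AOM/DSS samples lay below both controls on 19 of 19 autosomes, with differences from -1.15 to -0.713 points, and chromosome X differed by -0.793 points. With 2 samples against 2, an exact permutation test cannot give a two-sided p below 0.333, which is the value found here.

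The difference depended on how methylated a region was. Regions averaging 70 to 90% over the 6 samples stood at 82.3% ± 0.371 (SD, n = 2) in control and 79.7% ± 0.143 in AOM/DSS, a difference of -2.57 points over 35559 regions. At 50 to 70% the difference was -2.65 points, at 30 to 50% it was -1.44 points and above 90% it was -1.12 points. The sign turned at regions under 10%, where control stood at 2.83% ± 0.0846 and AOM/DSS at 3.25% ± 0.398, and where AOM/DSS replicate 1 with 3.53% lay apart from replicate 0 with 2.97%. The difference there, 0.417 points, was 0.136 points without AOM/DSS replicate 1. Between 10 and 30% the 2 groups overlapped. By CpG density, the difference was -1.49 points in the lowest of 4 classes split at the quartiles and -0.311 points in the highest, where it was -0.193 points without control replicate 0. The level classes were chosen after the data had been seen, and with classes set by the curcumin samples, which take no part in this comparison, the difference at 70 to 90% was -2.55 points. Requiring at least 100 calls in each sample favours regions with many CpGs or deep coverage. It brought the difference over all regions to -0.468 points and that at 70 to 90% to -2.42 points.

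**Figure D1:**
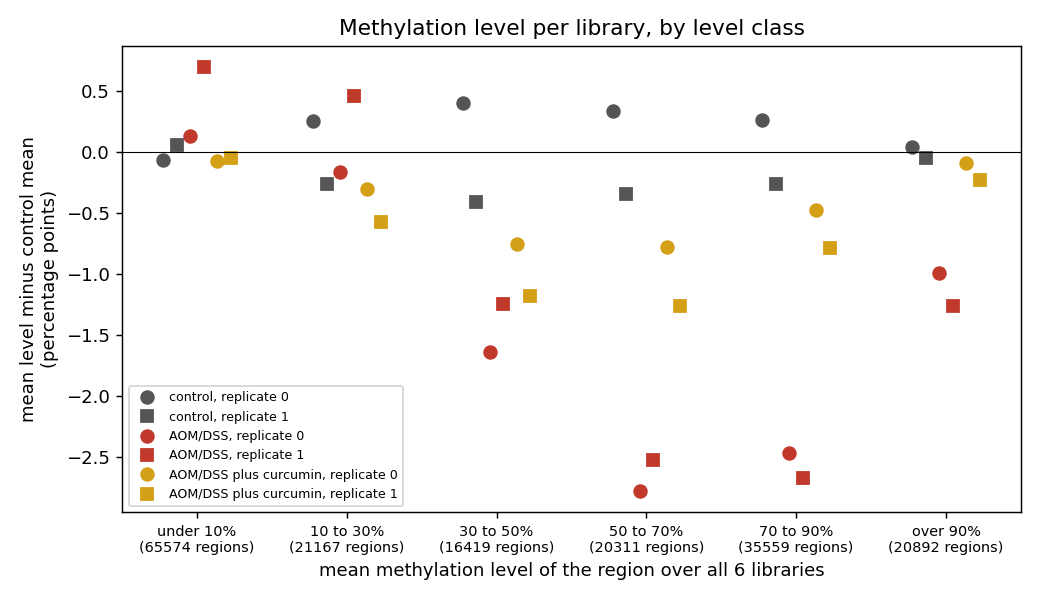
Mean methylation level per sample, in percentage points relative to the mean of the 2 control samples, for 6 classes of regions set by their level over all 6 samples; each symbol is a sample, colours are groups, and circles and squares are replicates 0 and 1. At 70 to 90% both AOM/DSS samples lay below both controls, by -2.57 points between the group means, and both curcumin samples lay between the 2 other groups.

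Of the 179922 regions, 7 differed by at least 10 points at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 5 of them lower and 2 higher in AOM/DSS. With only the 4 samples compared, the count was 1. It also changed in each of the 6 fits that left out 1 sample. Among these are the curcumin samples, which do not enter the difference but only the shared estimate of the spread. The changed count therefore does not by itself show that the calls rest on the values of single samples. The region on chromosome 19 from 21892566 to 21892986, with 12 CpGs, was called in 6 of these 6 fits. The remaining 6 regions each kept their call in at most 1 of the fits. Settings that use other tests gave from 0 to 3594 calls. The quasi-binomial model gave 9, 8 of them lower, and shared 4 with edgeR: the chromosome 19 region, 1 of each pair on chromosomes 17 (from 35338382) and 7 (from 139763677), and 1 on chromosome 10 (from 17403808).

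That chromosome 19 region (build mm9, as for all coordinates here) fell from 84.0% ± 0.999 (SD, n = 2) in control to 36.9% ± 5.005 in AOM/DSS, a difference of -47.1 points with an adjusted p of 0.000285 in edgeR, at 225 to 318 calls per sample. The next region on one side, from 21893122 to 21893376, stood at 96.0% and 72.5% without passing (edgeR adjusted p = 0.120). The next one on the other side, from 21892333 to 21892451, stood at 96.6% and 78.8%, also without passing (edgeR adjusted p = 0.640). With curcumin these 2 flanking regions stood at 90.3% and 80.5%, the latter near the AOM/DSS level. A pair of neighbouring regions on chromosome 17 fell as well. The first, from 35338139 to 35338267 with 5 CpGs, went from 57.2% ± 3.997 to 10.9% ± 3.64 (SD, n = 2; edgeR adjusted p = 0.0228), at 65 to 96 calls. The second, from 35338382 to 35338812 with 16 CpGs, went from 55.7% ± 3.83 to 21.4% ± 9.68 (SD, n = 2; edgeR adjusted p = 0.0392), at 389 to 516 calls. Another region within 1000 bases of them, from 35337598 to 35337831, stood at 73.3% in control and 37.7% in AOM/DSS but did not pass (edgeR adjusted p = 0.256). On the other side, the region from 35338934 to 35339172 was nearly unmethylated, at 0% in control and 1.49% in AOM/DSS.

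On chromosome 10, the region from 17403808 to 17403883 (4 CpGs, 181 to 284 calls) fell from 52.3% ± 7.44 to 15.8% ± 4.07 (SD, n = 2; edgeR adjusted p = 0.0255). The region from 77555505 to 77555773 on the same chromosome (13 CpGs, 171 to 365 calls) fell from 13.3% ± 6.51 to 1.28% ± 0.127 (SD, n = 2; edgeR adjusted p = 0.0228), and its control replicates were far apart, at 17.9% and 8.70%. Both regions that rose lie within 1000 bases of each other on chromosome 7. From 139763446 to 139763496 (5 CpGs, 109 to 174 calls) the level rose from 39.9% ± 4.36 to 80.5% ± 8.83 (SD, n = 2; edgeR adjusted p = 0.0392). From 139763677 to 139763700 (3 CpGs, 176 to 260 calls) it rose from 53.0% ± 5.39 to 86.5% ± 0.0887 (SD, n = 2; edgeR adjusted p = 0.0357).

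Among the regions that did not pass, those with the smallest unadjusted p, 5 per direction, had no overlap between the groups. On chromosome 14 the region from 32483017 to 32483176 stood at 81.3% ± 3.70 in control and 44.0% ± 6.74 in AOM/DSS (SD, n = 2; edgeR adjusted p = 0.0550). On chromosome 10 the region from 98544195 to 98544465 stood at 59.6% and 27.5%, on chromosome 12 the region from 36943573 to 36943825 at 78.3% and 49.1%, and on chromosome 16 the region from 28851826 to 28851934 at 94.2% and 69.8%. The last of the 5, on chromosome 10 from 41169589 to 41169949, had 6.32% in control and no methylated call among 234 and 262 calls in AOM/DSS. In the other direction, the region from 115672739 to 115672888 on chromosome 11 stood at 13.7% ± 7.53 in control and 49.2% ± 8.91 in AOM/DSS (SD, n = 2; edgeR adjusted p = 0.120). The region from 152655428 to 152655803 on chromosome 2 stood at 8.62% and 30.8%, and the region from 28783442 to 28783609 on chromosome 6 at 0.985% and 16.3%. The remaining 2 stayed low in both groups, at 1.92% and 7.65% on chromosome 17 from 75706492 to 75706934 and at 2.67% and 8.39% on chromosome 14 from 4518664 to 4519042. The quasi-binomial model called 3 of these 10, on chromosome 14 from 32483017 (adjusted p = 0.0457), chromosome 10 from 98544195 (adjusted p = 0.00905) and chromosome 12 from 36943573 (adjusted p = 0.00878).

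**Figure D2:**
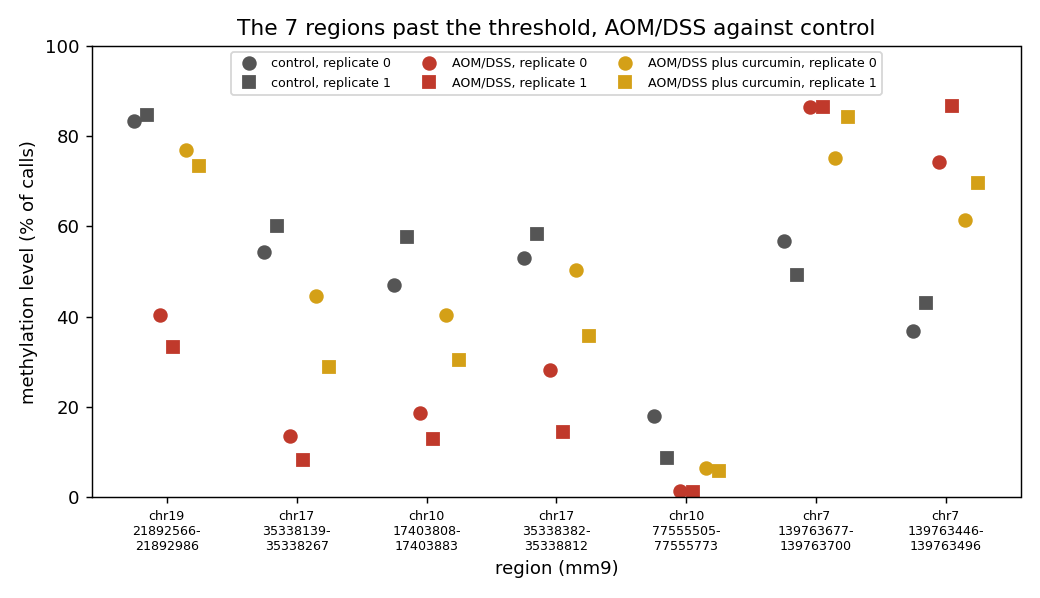
Methylation level in percent of each sample at the 7 regions called between AOM/DSS and control, 1 column per region; each symbol is a sample, colours are groups, and circles and squares are replicates 0 and 1. At the chromosome 19 region the controls had 83.3% and 84.7%, the AOM/DSS samples 40.4% and 33.3%, and the curcumin samples 76.99% and 73.3%.

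At an unadjusted p under 0.05 and a difference of at least 10 points, 5075 regions differed, 1301 higher and 3774 lower in AOM/DSS, so that 74.4% were lower. Without control replicate 0 there were 2369 higher and 4046 lower, and without AOM/DSS replicate 0 2295 higher and 3839 lower. Simulated unchanged groups gave a mean of 1924 such regions, of which 49.3% were lower. For counts of regions by level, here and in the second comparison, classes were set by the calls of all 6 samples pooled. This put 35611 regions at 70 to 90%. At 70 to 90% there were 1583 lower and 189 higher regions, against 394 and 403 in the simulated groups. At 10 to 30% both directions were in excess, with 484 lower and 464 higher regions against 183 and 208. At under 10% there were 176 higher and 59 lower regions, against 46.2 and 51.4, but the simulated spread was not estimated from regions at such levels. With no minimum difference the lower share was 57.0%.

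The second comparison, AOM/DSS plus curcumin against AOM/DSS, asks what curcumin changed under the same treatment. Methylated regions were more methylated in both curcumin samples than in both AOM/DSS samples, and no single region passed the test. The mean level over all regions was 40.8% ± 0.138 (SD, n = 2) with curcumin against 40.3% ± 0.192 without it, a difference of 0.482 points. Both curcumin samples lay above both AOM/DSS samples on 19 of 19 autosomes, by 0.366 to 0.628 points. At regions of 70 to 90% the level was 81.7% ± 0.219 with curcumin and 79.7% ± 0.143 without, a difference of 1.94 points. At 50 to 70% it was 1.63 points, above 90% it was 0.964 points, and at under 10% it was -0.474 points, or -0.192 points without AOM/DSS replicate 1. Between 10 and 30% it was -0.586 points, without overlap. The exact permutation test again gave its smallest two-sided p, 0.333. The difference over all regions was 0.186 points with at least 100 calls in each sample and 0.301 points with all reads pooled, while that at 70 to 90% was 1.76 and 1.84 points. Over all regions the 2 groups overlapped in both settings, with pooled levels of 31.04% and 30.5% with curcumin against 30.6% and 30.4% in AOM/DSS, whereas at 70 to 90% they stayed apart.

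In edgeR's test 0 regions were called between curcumin and AOM/DSS, with 9439 (5.25%) at an unadjusted p under 0.05. The quasi-binomial model called 2, limma 0, and Fisher's exact test on summed calls, which ignores the spread between samples, 1795. The smallest adjusted p, 0.0579 in edgeR, belonged to the chromosome 19 region that had fallen in AOM/DSS: it stood at 75.2% ± 2.59 (SD, n = 2) with curcumin, 38.3 points above AOM/DSS. The region passed without control replicate 0 (edgeR adjusted p = 0.0204) and without control replicate 1 (edgeR adjusted p = 0.0245), which made the count 1, and its adjusted p ranged up to 1 over the alternatives. The other region that the quasi-binomial model called lies on chromosome 11 from 53671303 to 53671626, with 57.9% ± 0.442 in curcumin, 30.5% ± 2.498 in AOM/DSS and 48.5% ± 2.57 in control (SD, n = 2).

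The regions with the smallest unadjusted p, 5 per direction, did not pass in edgeR, and their adjusted p ran from 0.0579 to 0.353. Higher with curcumin was the region from 138390509 to 138390711 on chromosome 4, at 88.7% ± 6.06 with curcumin, 58.1% ± 8.30 in AOM/DSS and 88.6% ± 1.62 in control (SD, n = 2). The region from 36493556 to 36493988 on chromosome 8 stood at 97.4% with curcumin, 81.4% in AOM/DSS and 92.1% in control. The chromosome 10 region from 41169589 to 41169949, without methylated calls in AOM/DSS, had 5.55% with curcumin. Lower with curcumin was the region from 78766136 to 78766509 on chromosome 11, at 6.36% ± 1.44 with curcumin, 22.7% ± 6.18 in AOM/DSS and 7.38% ± 1.70 in control (SD, n = 2). The region from 121325348 to 121325442 on chromosome 9 stood at 0.587% with curcumin, 10.4% in AOM/DSS and 2.24% in control. On chromosome 10 the region from 42481550 to 42481761 stood at 0.615%, 8.77% and 2.32%, in the same order. The last 2, on chromosome 17 from 75706492 to 75706934 and on chromosome 8 from 20020199 to 20020596, stood at 2.21% and 2.44% with curcumin and at 7.65% and 5.73% in AOM/DSS.

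At an unadjusted p under 0.05 and at least 10 points, 3595 regions differed, 2324 higher and 1271 lower with curcumin, against 1939 in simulated unchanged groups, split evenly. At 70 to 90% there were 1085 higher and 203 lower regions, against 387 and 404 in the simulated groups. At 10 to 30% there were 289 higher and 460 lower regions, against 198 and 198, and at under 10% 49 higher and 179 lower regions, against 50.6 and 49.8. For regions under 10% the simulated spread again came from regions at other levels. The lower share was 35.4%, and it turned to 51.3% when no minimum difference was required.

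Both of these comparisons hold the same 2 AOM/DSS samples with opposite sign, so opposite changes arise in part without any effect. At an unadjusted p under 0.05 and at least 10 points in both, 1105 regions changed in opposite directions, 795 lower in AOM/DSS and higher with curcumin and 310 the other way, and 1 region changed in the same direction. Simulated unchanged groups that share the AOM/DSS samples gave a mean of 250 opposite regions, and independent lists of these sizes would give 57.9. The count was 2186 without AOM/DSS replicate 0, which leaves a single shared sample, 681 without curcumin replicate 0 and 699 without curcumin replicate 1. At the adjusted threshold 0 regions were called in both comparisons by edgeR, and 1, the chromosome 19 region, without control replicate 0, without control replicate 1, with only the 4 samples compared, with a replicate block or with the quasi-binomial model. Across regions, which are not independent replicates, the 2 differences had r = -0.583, against -0.486 in the simulated groups. Their covariance was -16.9 squared points, against -11.3 in the simulated groups and -12.4 from the spread between the AOM/DSS replicates. Part of the excess may come from the shared samples.

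The shared samples were taken apart by choosing regions with 1 AOM/DSS and 1 control sample and measuring the difference to curcumin with the other AOM/DSS sample. Regions chosen as lower in AOM/DSS, 1365 to 2432 of them over the 4 choices, had a median difference between AOM/DSS and control of -4.24 to -1.99 points in the samples not used to choose, while all regions of matching level differed by -2.11 to -1.30 points. In 2 of the 4 choices the chosen regions were close to that, at -1.99 against -1.75 points and -2.14 against -1.61 points. In curcumin they lay above the unused AOM/DSS sample by a median of 2.02 to 3.397 points, while all regions of matching level did so by 0.705 to 1.11 points, so that the excess over them was 0.907 to 2.37 points. Against the unused control sample, curcumin differed by -1.18 to 0.154 points. Regions chosen as higher in AOM/DSS, 477 to 1373 of them, did not keep their direction in every choice: the medians ran from -1.58 to 2.44 points in the unused samples. All regions of matching level differed by -1.27 to -0.581 points, and the chosen ones lay above their level-matched value in 3 of the 4 choices. Their difference between curcumin and the unused AOM/DSS sample ran from -2.88 to -0.340 points.

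**Figure D3:**
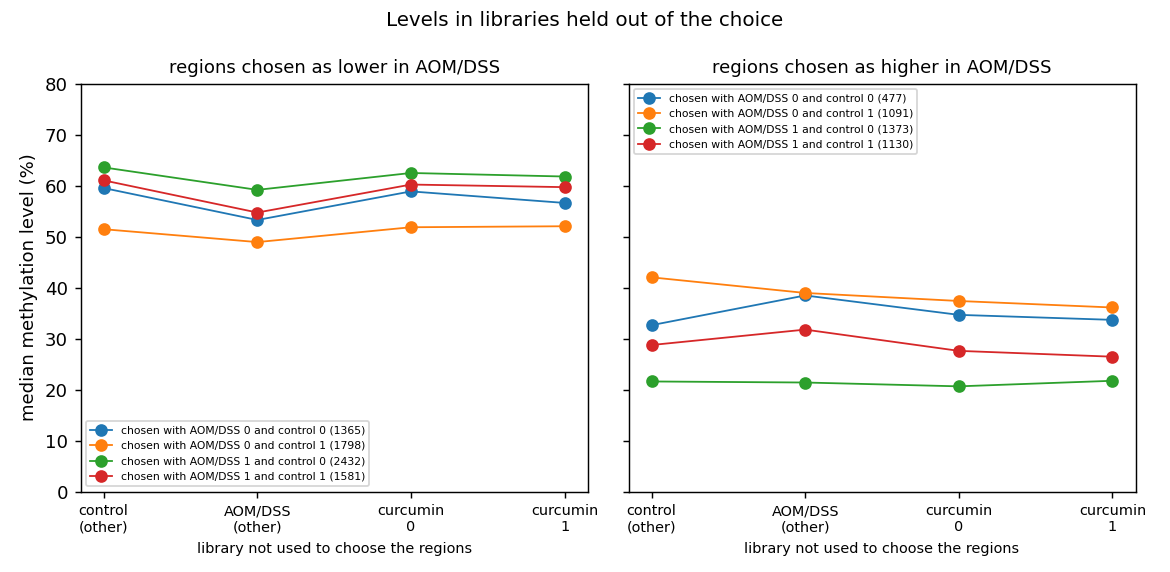
Median methylation level in percent, at regions chosen as lower (left) or higher (right) in 1 AOM/DSS sample against 1 control sample, in the 4 samples not used for that choice; each line is 1 of the 4 choices and the legend gives its number of regions. On the left the unused AOM/DSS sample had medians of 48.9 to 59.2%, below the unused control with 51.5 to 63.6% and below both curcumin samples in each choice.

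The third comparison, AOM/DSS plus curcumin against control, asks how far the curcumin samples stood from untreated mice. Their methylated regions lay slightly below control, by less than those of AOM/DSS, and no region passed the test. The mean level over all regions was 40.8% ± 0.138 (SD, n = 2) with curcumin and 41.2% ± 0.2002 in control, a difference of -0.417 points that was -0.275 points without control replicate 0. With all reads pooled the 2 groups overlapped, at 31.04% and 30.5% with curcumin against 31.00% and 31.3% in control. At 70 to 90% the pooled levels stayed apart. Both curcumin samples lay below both controls on 18 of 19 autosomes, the exception being chromosome 16. At 70 to 90% the difference was -0.626 points, and -0.364 points without control replicate 0. At 50 to 70% it was -1.02 points, and at under 10% the groups overlapped, at 2.78% ± 0.0159 with curcumin and 2.83% ± 0.0846 in control. Between 10 and 30% it was -0.436 points without overlap, and there curcumin lay below AOM/DSS as well. The exact permutation test gave a two-sided p of 0.333 for the mean level, the smallest possible.

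In edgeR's test 0 regions were called between curcumin and control, with 7507 (4.17%) at an unadjusted p under 0.05, and every adjusted p was 1. The quasi-binomial model and limma also called 0, and Fisher's exact test on summed calls 639. Without control replicate 0 a single region was called, on chromosome 11 from 96051326 to 96051653, 23.6 points higher with curcumin (edgeR adjusted p = 0.0281); it is named after its values were seen. Whether the count at an unadjusted p exceeded that of simulated unchanged groups depended on the minimum difference. With no minimum difference, the 7507 regions were fewer than the 7971 in the simulated groups. At an unadjusted p under 0.05 and at least 10 points, 2629 regions differed, 1011 higher and 1618 lower with curcumin, against 2007 simulated. Without control replicate 0 there were 1906 higher and 2325 lower.

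The 10 regions with the smallest unadjusted p, 5 per direction, did not pass. On chromosome 3 the region from 61962886 to 61963167 stood at 52.5% ± 4.16 with curcumin, 62.4% ± 7.34 in AOM/DSS and 86.3% ± 7.40 in control (SD, n = 2). The region from 5860292 to 5860492 on the same chromosome stood at 28.0%, 33.2% and 64.1%, in the same order, with the controls at 76.2% and 51.9%. On chromosome 16 the region from 93684596 to 93684777 stood at 6.31%, 9.45% and 26.9%. The chromosome 7 region from 139763677 to 139763700, which rose in AOM/DSS, stood at 79.8% ± 6.47 with curcumin against 53.0% ± 5.39 in control (SD, n = 2). On chromosome 11 the region from 11926084 to 11926286 stood at 42.5% ± 17.6 with curcumin, 26.9% ± 7.56 in AOM/DSS and 13.1% ± 3.74 in control (SD, n = 2). The chromosome 13 region from 58911367 to 58911380 stood at 98.5% with curcumin, 90.5% in AOM/DSS and 76.5% in control. On chromosome 4, the region from 129013551 to 129013884 stood at 7.27% with curcumin, 17.6% in AOM/DSS and 22.3% in control. The last 3 had group means under 5%, on chromosome 12 from 58649320 to 58649623, on chromosome 18 from 8694047 to 8694197 and on chromosome 4 from 129128917 to 129129016.

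At 7 of the 7 regions called between AOM/DSS and control, the curcumin mean lay between the means of the 2 other groups. The curcumin level was 36.7% ± 11.3 and 43.0% ± 10.4 at the chromosome 17 pair and 35.4% ± 7.05 and 6.13% ± 0.393 at the chromosome 10 regions (SD, n = 2). At the chromosome 7 pair it was 65.6% ± 5.87 and 79.8% ± 6.47, closer to AOM/DSS than to control. These regions were chosen for their AOM/DSS values, so a mean between the other groups can arise without any effect of curcumin.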

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

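The minimum of 50 or 100 calls, pooling without chromosome M, and leaving out samples for the mean levels, for 70 to 90%, for under 10% (also by CpG density) and for the highest CpG density were added after the data had been seen, as were all settings of the 70 to 90% level and opposite calls with only the 4 samples compared. The minima of 5 and 20 calls left the tested regions as they were and test nothing. The alternatives for gene lists were not run because no annotation of the build was used here. Where no value below shows a cause, the cause was not tested.

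AOM/DSS against control gave 7 calls. It gave 1 with at least 50 calls, 1 with at least 100 calls and 1 with only the 4 samples compared, each time the chromosome 19 region from 21892566 to 21892986. The quasi-binomial model gave 9, without the chromosome 17 region from 35338139 (adjusted p = 0.0672), chromosome 10 from 77555505 (adjusted p = 0.230) and chromosome 7 from 139763446 (adjusted p = 0.0511). Limma gave 0 and Fisher's exact test 3594. Leaving out samples gave 1 to 8, and the 3 calls without AOM/DSS replicate 0 were the chromosome 19 region, the chromosome 17 region from 35338382 to 35338812 and chromosome Y from 347050 to 347418. Without control replicate 1, the 2 were the chromosome 19 region and the chromosome 10 region from 77555505 to 77555773. Over the samples left out, the adjusted p of the chromosome 19 region reached at most 0.0438. The lower share at an unadjusted p was 57.0% with no minimum difference and 62.6 to 74.3% without a sample. Curcumin against AOM/DSS gave 0 calls, 2 with the quasi-binomial model, 1795 with Fisher's exact test, 1 with the 4 samples compared and 0 to 1 without a sample. Its lower share of 35.4% turned to 51.3% with no minimum difference and was 35.8 to 45.3% without a sample. Curcumin against control gave 0 calls, 639 with Fisher's exact test and 0 to 1 without a sample, and its lower share was 55.0 to 64.1%. Fisher's exact test takes no account of spread between samples.

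Opposite calls numbered 0, 1 with the quasi-binomial model, 1 with only the 4 samples compared and 0 to 1 without a sample. The 1105 opposite regions at an unadjusted p became 718 with at least 50 calls and 319 with at least 100, where fewer regions are tested, and 681 to 2186 without a sample. The mean level differences of -0.899 and 0.482 points became -0.468 and 0.186 with at least 100 calls, -0.664 and 0.301 with all reads pooled, and -0.640 and 0.278 pooled without chromosome M. Without a sample the 3 differences ran from -1.04 to -0.757, from 0.347 to 0.618 and from -0.558 to -0.275. At 70 to 90%, curcumin minus AOM/DSS was 1.76 with at least 100 calls. Without a sample the differences there ran from -2.83 to -2.31, from 1.79 to 2.10 and from -0.889 to -0.364.

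With the replicate block, AOM/DSS against control gave 41 calls (11 higher, 30 lower, with the 7 among them), curcumin against AOM/DSS 1, curcumin against control 0, and opposite calls 1. Deviations of samples with the same number had r = 0.0548 between control and AOM/DSS, 0.0121 between control and curcumin and 0.00754 between AOM/DSS and curcumin. These deviations also hold the draw of calls, so a low r does not exclude a batch shared by samples of the same number. What the numbers stand for is not given in the labels.

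Single named regions never changed direction, but they could not have done so. The difference is that of the group means under every test, and the groups did not overlap at these regions. Neither another test nor leaving out a sample can therefore turn its sign, so the kept direction tests nothing. For the named regions, values under alternatives other than the minima of 5 and 20 calls were compared with the threshold. Of these values, 433 planned and 55 added ones kept their side of it. Another 35 planned ones came past it, and 50 planned and 11 added ones no longer passed.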

Other observations

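The tests on conversion, constant rates and neighbours were chosen after the results had been seen, as was the comparison with regions of matching level for the shared samples. The test on cell types was chosen before.

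AOM/DSS replicate 1 held more gains confined to a single sample than any other sample did. Of 57412 regions under 10% in the other 5 samples, 23 stood at 25% or more in it, against 2 to 6 such regions in each of the other samples. A cluster lies on chromosome Y from 346418 to 347418, where its 3 regions had 27.9%, 11.6% and 22.9% in AOM/DSS replicate 1 and 0 to 5.79% in the other samples, at 28 to 261 calls. The last of the 3, from 347050 to 347418, was called higher in AOM/DSS when AOM/DSS replicate 0 was left out (edgeR adjusted p = 0.00418). These regions were singled out after their values were seen.

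At regions under 10% in curcumin, the AOM/DSS mean lay above the control mean in each of 4 classes of CpG density. In the highest class, with 27543 regions, the difference was 0.244 points and both AOM/DSS samples, at 2.32% and 2.52%, lay above both controls, at 2.17% and 2.18%. In the next class it was 0.414 points, again without overlap. In the lower 2 classes it was 0.626 and 0.795 points, and the groups overlapped. AOM/DSS replicate 1 was the higher of the 2 AOM/DSS samples in each class, and without it the differences shrank to 0.140, 0.132, 0.127 and 0.121 points, from the highest class of density to the lowest.

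The lower level of methylated regions in AOM/DSS was spread over many regions. At 70 to 90%, by the level in curcumin, the difference between AOM/DSS and control had a median of -2.41 points over 34466 regions, a lower quartile of -6.22 and an upper quartile of 1.17, and 67.4% of regions were lower. Better bisulfite conversion is argued against by the low level of unmethylated DNA in the controls, at most 0.991% at mitochondrial regions and 2.18% at the CpG-dense regions above. Had a control held that many unconverted cytosines, complete conversion would lower the 70 to 90% class by at most 0.408 points, while the smallest difference between a control and an AOM/DSS sample there was 2.20 points. Methylated cytosines read as unmethylated at a constant rate, or unmethylated calls added in proportion to all calls, would lower all levels in proportion, but the relative fall was 4.26% at 50 to 70% and 1.41% above 90%, a ratio of 3.02. Methylated calls lost at a constant rate would shift the log odds of methylation alike at every level, but the shift was 0.00445 at 10 to 30% and -0.162 at 70 to 90%, without overlap between the 4 pairs of samples. A loss at a rate that differs between regions is not excluded by these values. A different share of cell types in the scraped tissue may also lower methylated regions, and this cannot be told apart from a change within epithelial cells, because 0 marker regions could be located without an annotation of the build. The treatment, the colitis and any batch shared by the 2 samples of a group stay open as well.

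That regions lower in AOM/DSS stood higher with curcumin could come in part from chance values of the shared AOM/DSS samples. Chance values drawn separately for each region are argued against, as the only source, by the 795 such regions. Simulated unchanged groups with 1 common spread gave 102 to 124. The covariance of the 2 differences, -16.9 squared points, also went past the -12.4 from the spread between the AOM/DSS replicates. Neither the simulation nor that spread holds a shift common to many regions of both AOM/DSS samples, so such a shift is not excluded. In the AOM/DSS sample not used to choose regions, curcumin lay above by medians of at least 2.02 points in each of the 4 choices, but regions of matching level lay above as well. The excess over them was at least 0.907 points, which is less than the range of 1.46 points over the 4 choices, and the choices reuse the same 2 AOM/DSS samples. By the samples not used to choose, chance values are therefore not excluded. A difference in cell types or in severity of the colitis between the groups would give the same picture and was not tested.

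Differences at neighbouring regions went together only weakly. Across 28378 pairs less than 500 bases apart, with the first region of a pair averaging 20 to 95%, r was 0.140 for AOM/DSS minus control, 0.136 for the difference between the control replicates, 0.0512 for the AOM/DSS replicates and 0.0163 for the curcumin replicates. Across 6773 pairs 500 to 1000 bases apart it was 0.0903 for AOM/DSS minus control and 0.0571, 0.0315 and -0.00473 for the replicates. Whether a group effect spans neighbouring regions stays undecided, because the control replicates alone came close to the group difference at the shorter distance.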
